A study of Mus musculus with 2 samples.

How the data were processed

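CMT-93 is a mouse rectal carcinoma cell line. Per the labels' protocols, CMT-93 cells were injected into the tail veins of 6-week-old female mice, lung tumours were recovered 8 weeks later, and the recovered cells were cultured as CMT-93-PM1. Total RNA from each culture, 6 µg per array, was converted to biotin-labelled cRNA by the Affymetrix protocol. There was 1 array of parental CMT-93 and 1 array of lung-recovered CMT-93-PM1.

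The deposited values were log2 signals with 2 decimals for 45037 probe sets per array. The base of the logarithm was taken from the values: base 2 puts the brightest signals at 19484 and 19893 on a linear scale, within a scanner's range. The submitters' processing notes name MAS5 with no role. The ratio between the arrays had an SD of 0.22 in the dimmest of 10 equal bins of mean signal and 0.76 in bin 7. MAS5 signals usually scatter most at the dim end, so the method that summarised probes into these signals is not settled here. How the authors made the arrays comparable is not given in the sources used here, and the deposited columns differed by at most 0.11 log2 at any quantile. The 2% trimmed means on the linear scale were 233 and 243, a difference of 4.13% that lay inside the 5% limit set for using values without rescaling. The values were therefore used as deposited.

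Each array was floored at its own 40th percentile, 4.69 log2 for the parental array and 4.59 for the lung-recovered array, since no detection calls were used here. A gene at the floor on both arrays was not measured. A gene at the floor on 1 array has only a bound on its fold difference, computed against the floor of that array and written "at least N-fold". Log2 ratios are lung-recovered minus parental, so positive values are higher in the lung-recovered line. Floors also limit the precision of dim genes, and a single array per group limits that of all others.

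Probe sets were named through a platform annotation that lists 35877 of the 45037, and its symbols were updated by Entrez identifier to the mouse gene table of assembly GRCm38.p6. Of the listed probe sets, 34945 had 1 symbol and 932 had several. Of those with 1 symbol, 34741 matched the gene table and 204 kept the older symbol. The 9160 probe sets that the annotation does not list are unnamed here, and those with several symbols were not named either. This left 18193 genes. Of these, 9010 had more than 1 probe set and were represented by the probe set with the highest mean signal. Among 6172 genes with several probe sets above the floor, the median SD of the log2 ratio between probe sets of 1 gene was 0.18, and the 90th percentile of that SD was 0.52. That spread is technical and within array, and it is the only spread these data contain. Actin and Gapdh control ratios and hybridization spikes were planned as array checks and were not analysed here, since the table used holds 0 control probe sets.

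With 1 array per group there is no replicate check of any difference, no test between conditions and no p-value. Genes were counted by size, at 2-fold or more in either direction. For 27 gene lists fixed before the data were examined, the median log2 ratio of the measured members was placed among 10000 random lists of the same size, matched on mean log2 signal in 20 bins. A list with at least 5 measured members was called apart when its median lay among the lowest 2.5% or the highest 2.5% of them. Such a percentile describes these arrays and is no test of the conditions. Of 995 list symbols, 903 matched a gene of the annotation, 6 of them through an older name. The matching of older names was corrected after list values had been seen, because it had paired some list symbols with other genes, and no list crossed a limit through that correction. Medians per chromosome were handled in the same way, with chromosomes and gene order taken from GRCm38.p6. Positions of that assembly served only to order genes, and no coordinates are given.

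Genes named in the text follow a rule fixed before the data were examined. It takes the 4 profilin genes and the 10 genes furthest apart in each direction among those above the floor on both arrays. It also takes the 5 highest bounds in each direction. Both steps keep a gene only if its other probe sets have the same sign and a log2 ratio of at least 0.5 in size. The first compares only probe sets above the floor on both arrays, so it did not weigh the dim probe set of Cyp1b1, and the second those above the floor on at least 1. Up to 4 members of each list that stood apart are named, up to 2 past the 2-fold rule from every other list, and the brightest marker of each list for a non-tumour cell type. The rule passed over Cd82 and Tenm2 as top genes because their probe sets disagreed. Other genes named were chosen after their values were seen, and this is said where they appear.

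The alternatives were scaling to equal medians, quantile normalization, lowess of the ratio on the mean signal with a span of 0.3, floors at the 20th and 60th percentiles, no floor with a pseudocount of 1, the median over the probe sets of a gene, leaving out probe sets with the suffix _s, _x or _a, list means, unmatched random lists or sets, and lists without shared members. After seeing the data, lists without genes of chromosome 12, chromosomes without genes past the 2-fold rule and random sets without genes of chromosome 12 were added. Simulated ratios were those of the 13332 measured genes shuffled among genes of similar signal, so genes varied independently, which members of a real list need not do. Of 200 unshifted sets of 30 genes, 3% were called apart. A shift of 0.2 log2 was called in 63% of such sets, a shift of 0.3 in 94% and a shift of 0.5 in 100%. Of 10 unshifted sets of 450 genes, near the size of a chromosome, 10% were called apart, and 4.5% of 200 in a larger run added after seeing the data, where a shift of 0.05 was called in 69.5%. The 2-fold rule called 0% of 200 genes with a simulated change of 0.5 log2, 100% at 1.5 and 100% at 3, and 0 of 17993 genes left unchanged. The changed genes were drawn only from those above the 60th percentile of the parental array, so recovery of dimmer genes was not checked. The unchanged genes included those at the floor on both arrays. The noise in that simulation was the median spread between probe sets alone, so these outcomes were near certain and give no rate of false calls between 2 single arrays. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.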

Results

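The series compared cells recovered from lung tumours with the colorectal carcinoma line they came from, to find genes whose expression differs between a lung-metastatic derivative and its parent. Its title names profilin 2. Parental CMT-93 and lung-recovered CMT-93-PM1 cells were each profiled on 1 array, so the differences describe these 2 cultures and have no replicate error, and effects of culture, labelling or hybridization on a single array cannot be told apart from the difference between the lines. Median signals were 5.36 log2 on the parental and 5.26 log2 on the lung-recovered array, and the signals of the 45037 probe sets correlated with Pearson's r of 0.980 across probe sets, which are not independent replicates.

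Pfn2, an actin monomer-binding protein of the profilin family, was at the floor in the parental line and strongly expressed in the lung-recovered line. Its representative probe set (1418210_at) read 4.29 log2 on the parental and 9.78 on the lung-recovered array, at least 34.1-fold higher. The other Pfn2 probe sets gave the same direction, with 1418209_a_at at 3.30 and 10.24, at least 46.9-fold higher, and 1436993_x_at at 4.73 and 8.71, 15.8-fold higher and above the floor on both arrays. Pfn1, the widely expressed profilin, read 12.19 and 12.22. Pfn3 (3.39 and 3.93) and Pfn4 (3.09 on the parental array) were at the floor on both arrays and were not measured. The probe sets were not assigned to Pfn2 isoforms, since no probe sequences were used here. The size of the Pfn2 bound depends on the floor, with a log2 ratio of 5.09 as reported and 3.60 with the floor at the 60th percentile.

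The transmembrane protein gene Tm4sf1 had the larger bound by its brightest probe set, at 4.56 and 11.50 log2 or at least 112-fold higher, while its other probe sets were at least 12.6-fold (4.44 and 8.34) and at least 4.44-fold (3.75 and 6.84) higher. By the median over probe sets its log2 ratio was 3.65, below that of Pfn2. Plac8 read 5.68 and 10.96 and was 38.9-fold higher, and Cldn2, which encodes a pore-forming tight junction protein, read 6.97 and 11.42 and was 21.9-fold higher (9.19-fold by its other probe set). By representative probe set, the largest difference downward among genes above the floor on both arrays was that of the aldo-keto reductase gene Akr1c18, at 12.05 and 6.81, or 37.8-fold lower in the lung-recovered line. Timp3, a tissue inhibitor of metalloproteinases, read 8.75 and 4.76 and was 15.9-fold lower (from at least 7.73-fold to 16.1-fold by its other probe sets), or -2.60 log2 with the floor at the 60th percentile. Of 13332 measured genes, 508 were at least 2-fold higher and 286 at least 2-fold lower with signal above the floor on both arrays. A further 81 were higher from the floor of the parental array and 54 lower to the floor of the lung-recovered array. Of all 929 genes past the rule, 63.4% were higher. At 4-fold or more the counts were 72 higher and 61 lower. Another 4861 genes were at the floor on both arrays.

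Among the other genes furthest upward, Dynap (12.9-fold), Hsf2bp (5.78 and 9.37 log2, and 2.36-fold by a dimmer probe set), the crystallin gene Crybb1 (11.8-fold), the serine protease gene Tmprss11e (6.07 and 9.53 log2), the keratin-associated protein gene Krtap1-5 (10.1-fold), the collagen gene Col8a1 (8.51-fold, and 4.47-fold and at least 2.71-fold by its other probe sets) and Map1lc3a (8.11-fold, and 2.99-fold by its other probe set) were all above the floor on both arrays. Cyp1b1, a cytochrome P450 monooxygenase, was 17.8-fold higher by its brightest probe set and at least 4.56-fold higher by another, while its remaining probe set read 4.57 and 4.72. From the floor of the parental array, the cadherin-related gene Cdhr2 was at least 27.3-fold, the endothelial cadherin gene Cdh5 at least 24.4-fold (at least 1.78-fold by a dimmer probe set) and the glycosyltransferase gene Gcnt1 at least 23.6-fold higher (at least 1.95-fold by its other probe set). Downward, the glucuronosyltransferase genes Ugt2b36 (31.6-fold) and Ugt2b34 (16.1-fold), the cornified envelope gene Sprr1b (25.1-fold), the transcription factor gene Sox17 (23.8-fold, and at least 58.1-fold by its other probe set), Ndrg4 (18.9-fold), the Na,K-ATPase regulator gene Fxyd2 (16.3-fold, and at least 38.6-fold and at least 17.3-fold by others), the noncoding RNA Snhg4 (12.6-fold) and Akr1c14 (9.33 and 5.75 log2) followed Akr1c18. Rps6ka6 was at least 29.0-fold (at least 2-fold by a dimmer probe set, at 5.59 and 4.03), the phosphodiesterase gene Pde8b at least 20.1-fold, the transporter gene Slc6a12 at least 16-fold and the angiopoietin receptor gene Tek at least 15.8-fold lower, and Rnls read 8.17 and 3.49. With the floor at the 60th percentile these bounds shrank, to log2 ratios of 3.28 for Cdhr2, 3.12 for Cdh5, 3.07 for Gcnt1, -3.30 for Rps6ka6, -2.77 for Pde8b, -2.44 for Slc6a12, -2.42 for Tek and -2.02 for Rnls, and Cyp1b1 was at 2.68, Dynap at 3.09, Crybb1 at 2.82, Sox17 at -3.65 and Fxyd2 at -3.26. The Ugt2b, Akr1c and Sprr genes have close paralogs, so their signals may include those of relatives and the assignment to 1 member is uncertain.

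**Figure D1:**
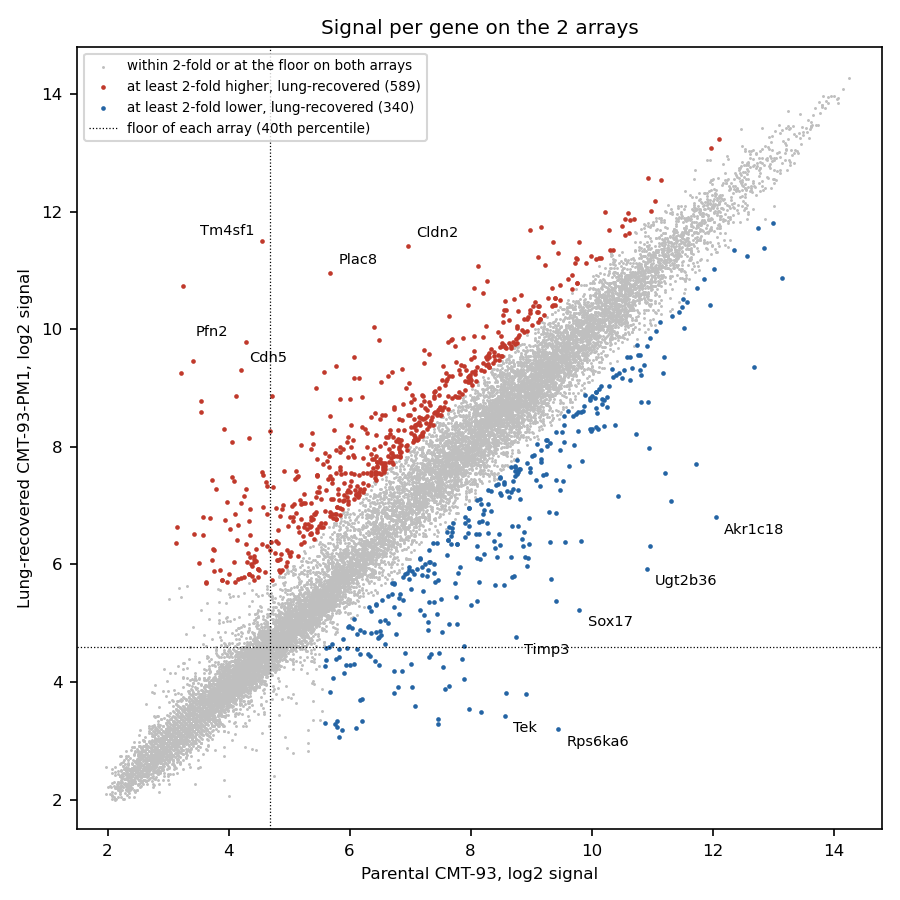
Log2 signal of each gene on the parental array (horizontal axis) and on the lung-recovered array (vertical axis), with 1 point per gene at its representative probe set and dotted lines at the floors of 4.69 and 4.59. Red points are the 589 genes at least 2-fold higher and blue points the 340 at least 2-fold lower in the lung-recovered line, with Tm4sf1 and Pfn2 left of the parental floor.

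Of the 25 fixed gene lists with enough measured members, 5 stood above and 4 below random lists of matched signal. If genes varied independently, 1.25 would lie outside these limits. Members of a list need not vary independently and some lists share members, so 1.25 is only a rough reference. The lists of integrins, laminins and adhesion receptors, of endoplasmic reticulum and heat stress genes, of epithelial junctions and keratins, of actin assembly and of growth factor receptors and ligands had raised medians. The lists of hypoxia and glycolysis, oxidative phosphorylation, cytosolic ribosomal proteins and lung epithelial markers had lowered medians.

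In the list of integrins, laminins and adhesion receptors, 5 of 37 measured genes were at least 2-fold higher and 0 lower, with a median log2 ratio of 0.31 at percentile 99.97 of random lists. The tetraspanin gene Cd82 read 6.40 and 10.03 by 1 probe set, 12.4-fold higher, but 7.32 and 7.22 by its other. The adhesion molecule gene Vcam1 (7.11-fold, at least 16.6-fold by a second probe set, and 1.85 log2 with the floor at the 60th percentile), the basement membrane collagen gene Col18a1 (5.98-fold, and 17.9-fold by its other probe set) and Itga6, which encodes a laminin-binding integrin subunit (4.17-fold), were higher, as was the laminin gene Lamb3 (3.23-fold, chosen after its value was seen). In the actin assembly list, 1 of 48 genes passed 2-fold, the formin gene Diaph2, at 6.86 and 9.33 or 5.54-fold higher. Its median was 0.21 (percentile 99.69), with 35 genes above 0 and 11 below. The bundling protein gene Fscn1 (11.91 and 12.87) and Wasf1 (8.72 and 9.68) had ratios of 0.96, and the plastin gene Lcp1 of -0.90. Neither list kept its place without probe sets of suffix _s, _x or _a, at percentile 95.63 for integrins, laminins and adhesion receptors and 88.61 for actin assembly.

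Among epithelial junction and keratin genes, 5 of 37 were higher and 2 lower, with a median of 0.22 (percentile 98.58). Beside Cldn2, the protease inhibitor gene Spint1 was 2.38-fold higher, while the epithelial transcription factor gene Ehf (7.52-fold) and the desmosomal cadherin gene Dsg2 (4.53-fold, with its other probe sets from 2.93-fold to at least 7.36-fold) were lower. The list was within the random range after quantile normalization, without a floor and without the suffixed probe sets, at percentiles 96.38, 97.29 and 87.03. Among growth factor receptors and ligands, 7 of 44 were higher and 1 lower, with a median of 0.21 (percentile 99.03, and 96.71 with the floor at the 60th percentile). The lymphangiogenic growth factor gene Vegfc (4.35-fold), the IGF-binding protein gene Igfbp4 (4.32-fold, with its other probe sets from 1.68-fold to at least 14.9-fold), Pdgfb (3.39-fold, but 1.65-fold by its other probe set and a log2 ratio of 0.40 with the floor at the 60th percentile) and the mannose 6-phosphate receptor gene Igf2r (3.16-fold) were higher. Among endoplasmic reticulum and heat stress genes, 4 of 32 were higher and 1 lower, with a median of 0.27 (percentile 99.85). The higher ones were the endoplasmic reticulum genes Sdf2l1 (3.39-fold), Creld2 (2.43-fold) and Pdia6 (2.48-fold by its brighter probe set, 1.21-fold by a dim one, and 0.79 log2 by their median) and, chosen after its value was seen, the stress transcription factor gene Ddit3 (2.38-fold). The heat shock gene Hspa1b, which has a near-identical neighbour, was 3.84-fold lower.

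Of 31 hypoxia and glycolysis genes, 25 had ratios below 0, with a median of -0.34 that 0 percent of random lists reached. Past 2-fold, Ankrd37 (2.62-fold, but a log2 ratio of -0.09 with the floor at the 60th percentile), Ddit4 (2.31-fold), the phosphofructokinase gene Pfkl (2.27-fold, with its other probe sets at 1.96-fold and 1.72-fold) and, chosen after its value was seen, Bnip3 (2.17-fold) were lower. Pfkfb3, whose enzyme makes an activator of glycolysis, was 5.35-fold higher, and 2.07-fold by its dimmer probe set. Of 43 oxidative phosphorylation genes, 37 had ratios below 0 and 0 passed 2-fold in either direction, with a median of -0.29 (percentile 0). The largest ratios in this list were those of the respiratory chain genes Uqcrfs1 (12.06 and 11.31), Ndufb8 (11.71 and 10.98), Ndufb2 (11.52 and 10.85, while a dim probe set read 5.23 and 5.05) and Cyc1 (12.46 and 11.82). Of 28 cytosolic ribosomal protein genes, 25 had ratios below 0, with a median of -0.17 (percentile 0.65). Rpl12 was 3.25-fold lower, and Rpl14 (9.35 and 8.45), Rps9 (13.23 and 12.71) and Rps3 (13.34 and 12.83) had smaller ratios. A dim probe set of Rps3 read 5.65 on both arrays and one of Rps9 was at least 3.27-fold lower, and ribosomal protein genes have many processed copies that can share signal.

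**Figure D2:**
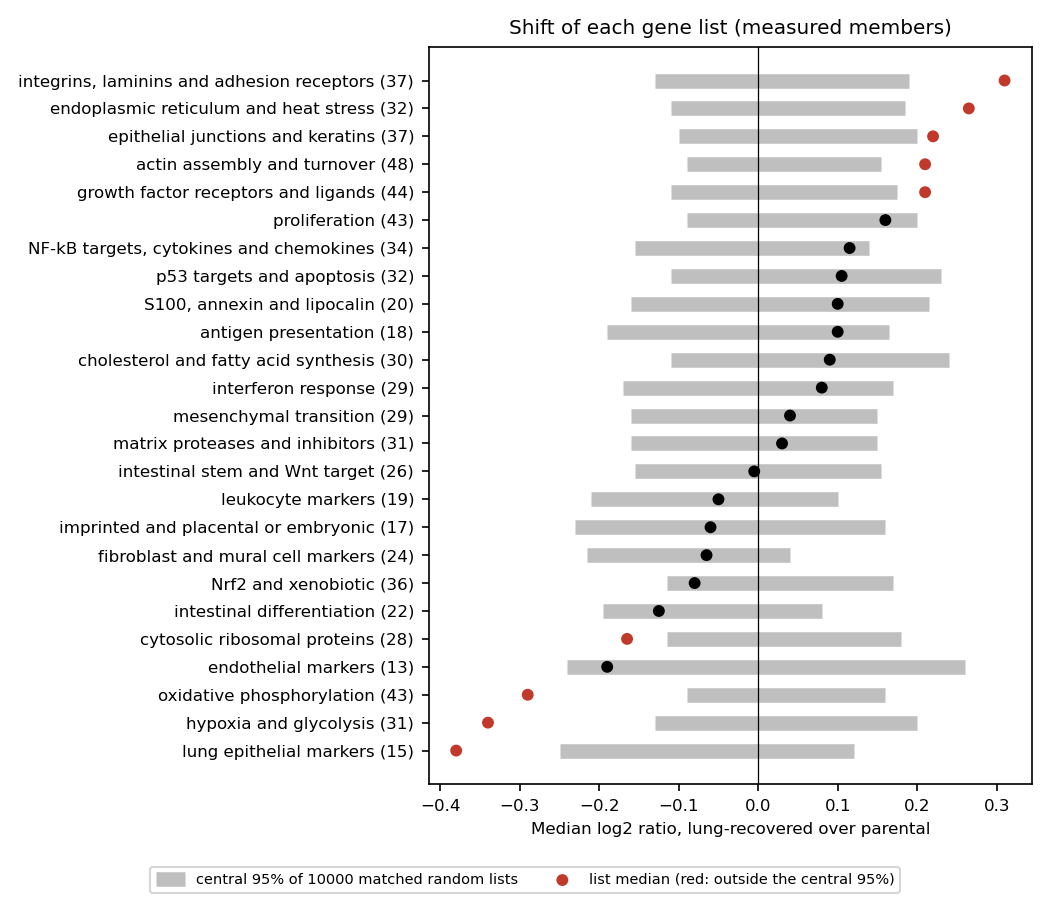
Median log2 ratio (lung-recovered over parental, horizontal axis) of the measured members of each of 25 gene lists, with the number of members in parentheses. Grey bars span 10000 random lists matched on signal without their outer 2.5% on either side, and red points mark the 9 lists outside that range, from -0.38 for lung epithelial markers to 0.31 for integrins, laminins and adhesion receptors.

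Genes of the cell types of the host lung were not higher as groups. Of 15 measured lung epithelial markers, 1 was higher and 1 lower past 2-fold, and the median was -0.38 (percentile 0.03, and 4.13 for the list mean). The aspartic protease gene Napsa was 4.14-fold lower and Rtkn2 at least 3.51-fold higher (a log2 ratio of 0.32 with the floor at the 60th percentile). Abca3 (7.99 and 8.73, with ratios of 0.74 and 0.42 by 2 probe sets), Ager (6.15 and 5.45, with a dim probe set at 5.30 on both arrays) and the brightest marker, the water channel gene Aqp5 (10.68 and 10.01), were within 2-fold. Of these markers, 13 of 21 on the array were above the floor in the parental line already. Of 24 measured fibroblast and mural cell markers, 0 passed 2-fold, with a median of -0.07 (percentile 67.23) and Des brightest at 6.78 and 6.23. Of 13 measured endothelial markers, Cdh5 was higher and both Sox17 and Tek were lower, with a median of -0.19 (percentile 6.83, and 0.74 for the list mean) and Esam brightest at 8.93 and 8.70. Of 19 measured leukocyte markers, Cd68 (3.53-fold, but a log2 ratio of 0.87 with the floor at the 60th percentile) and Csf1r (2.17-fold by its brightest probe set, with its others within 2-fold, chosen after its value was seen) were higher, and Plek (4.26-fold, and 1.79-fold and at least 2.87-fold by its other probe sets, and -1.08 log2 with that floor), Cd14 (2.81-fold, the brightest) and Cd74 (2.97-fold) were lower, with a median of -0.05 (percentile 59.39, and 0.1 with that floor). The list of sex-linked transcripts had 0 measured members.

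The lists of mesenchymal transition, matrix proteases, intestinal differentiation, and intestinal stem and Wnt target genes did not stand apart by their medians under the main settings. Of 29 measured mesenchymal transition genes, 4 were higher and 1 lower (percentile 74.14). The list stood above random lists under 5 of 12 alternatives, such as its mean (percentile 99.38) and its median without members shared with other lists (99.98). Tgfb3 was 5.54-fold higher (1.41 log2 with the floor at the 60th percentile), and the matricellular gene Ccn1 was 2.62-fold higher by 2 probe sets and 1.14-fold and 1.17-fold by the others, and 0.81 log2 by their median. Of 31 matrix proteases and inhibitors, 1 was higher and 4 lower (percentile 71.59), and the list mean lay on the other side, below random lists at percentile 1.64. The membrane-type metalloproteinase gene Mmp14 was 4.79-fold higher while Timp3 was lower. The rest of those lower past 2-fold, named after their values were seen, were protease genes. By representative probe set these were Mmp12 (4.35-fold), Mmp13 (at least 4.44-fold) and Adamts1 (2.51-fold). Of 22 intestinal differentiation genes, 2 were higher and 1 lower (percentile 19.6), among them the gut peptide gene Guca2a (3.89-fold higher) and the carbonic anhydrase gene Car2 (13.15 and 10.87, 4.86-fold lower). Of 26 intestinal stem and Wnt target genes, 2 were higher and 0 lower (percentile 51.91), the stem cell receptor gene Lgr5 (4-fold) and Rnf43 (2.77-fold), both known Wnt targets. The list medians and means of the matrix protease list (0.03 and -0.18) and the stem and Wnt list (-0.01 and 0.15) differed in sign.

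The medians of inflammatory and immune lists also stayed within the random range. Of 34 NF-kB target, cytokine and chemokine genes, 3 were higher and 7 lower, among them the cytokine gene Il6 (7.89 and 4.61, close to the floor, 9.71-fold lower, and -1.74 log2 with the floor at the 60th percentile) and the chemokine gene Ccl2 (at least 7.73-fold lower, and -1.39 log2 with that floor), with a median of 0.12 and a mean of -0.12 (percentile 95.32, and 99.23 after quantile normalization). Of 29 interferon response genes, 2 were higher and 2 lower (percentile 84.99, and 98.37 with the floor at the 60th percentile), with Oas1a 2.87-fold and Mx1 at least 2.68-fold lower. Their median was 0.08, with 18 ratios above 0 and 11 below. Of 18 antigen presentation genes, 0 were higher and 2 lower past 2-fold (percentile 90.97), Cd74 and the immunoproteasome gene Psmb10 (2.33-fold). The median was 0.10, with 10 ratios above 0 and 8 below. Among those above 0, chosen after their values were seen, were H2-K1 (0.57), H2-D1 (0.62) and B2m (0.66). Of 20 S100, annexin and lipocalin genes, 1 was higher and 4 lower, including S100a1 (2.85-fold) and Anxa8 (2.79-fold, but 1.65-fold by its other probe set), with a median of 0.10 and a mean of -0.16 (percentile 79.47).

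Of 43 proliferation genes, 0 passed 2-fold in either direction (median 0.16, percentile 92.59, and 98.11 among unmatched random lists), with 30 ratios above 0 and 13 below. They ran from -0.69 for Cenpa to 0.81 for Mcm2 and E2f1, named after their values were seen. Of 32 p53 target and apoptosis genes, 4 were higher and 0 lower (percentile 72.52), including Zmat3 (3.58-fold) and the antiapoptotic gene Bcl2 (2.89-fold, with further probe sets at 2.71-fold, 1.40-fold and 1.28-fold and their median under 2-fold). Of 36 Nrf2 and xenobiotic genes, 7 were higher and 5 lower, including Cyp1b1 upward and the glutathione transferase gene Gsta2, a member of a family of close paralogs, downward (5.82-fold), with a median of -0.08 and a mean of 0.10 (percentile 7.62). Of 30 cholesterol and fatty acid synthesis genes, 3 were higher and 0 lower (percentile 62.59), including the mevalonate pathway gene Mvd (2.30-fold, but 1.78-fold by its other probe set) and the fatty acid desaturase gene Fads2 (2.17-fold, with others at 2.19-fold and 1.73-fold). Of 17 imprinted, placental or embryonic genes, only Igf2r passed 2-fold, with a median of -0.06 and a mean of 0.06 (percentile 47.55).

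Genes of chromosome 12 were higher as a group in the lung-recovered line. The median log2 ratio of its 452 measured genes was 0.27, or 1.21-fold, at percentile 100 of matched random sets, and 39 of them were at least 2-fold higher while 2 were lower. The next largest median was that of chromosome 3, the chromosome of Pfn2 and Tm4sf1, at 0.08 (percentile 100), with 40 genes higher and 22 lower. Chromosomes 6 (-0.06, percentile 0.01), 15 (-0.06, percentile 0.21) and 16 (-0.05, percentile 0.53) had medians below random sets. The other 15 of the 20 chromosomes, the X included, did not stand apart. If genes varied independently, 1 would be expected outside the limits. Chromosome 6 was within the random range after quantile normalization (percentile 3.79), and chromosome 15 after quantile normalization (2.56), after lowess (3.36) and with the floor at the 60th percentile (8.87).

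**Figure D3:**
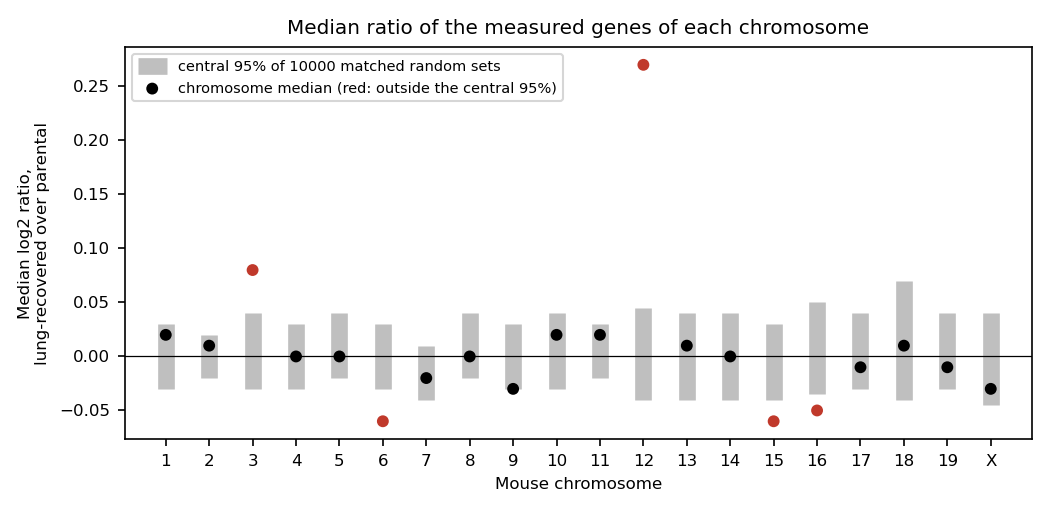
Median log2 ratio (lung-recovered over parental, vertical axis) of the measured genes of each mouse chromosome. Grey bars span 10000 random gene sets matched on signal without their outer 2.5% on either side, red points lie outside, and chromosome 12 lies highest at 0.27.

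Of the 20 measured genes nearest to Pfn2 on chromosome 3, 10 on each side, 16 were within 2-fold, 4 were higher and 0 lower, with a median log2 ratio of 0.18. Tm4sf1 is among these neighbours, and the 5 measured genes between Tm4sf1 and Pfn2 had ratios from -0.14 to 0.41. The others past 2-fold, named after their values were seen, were Nbea (8.78 and 10.31), Med12l (3.79 and 7.28) and P2ry12 (4.45 and 6.26).

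**Figure D4:**
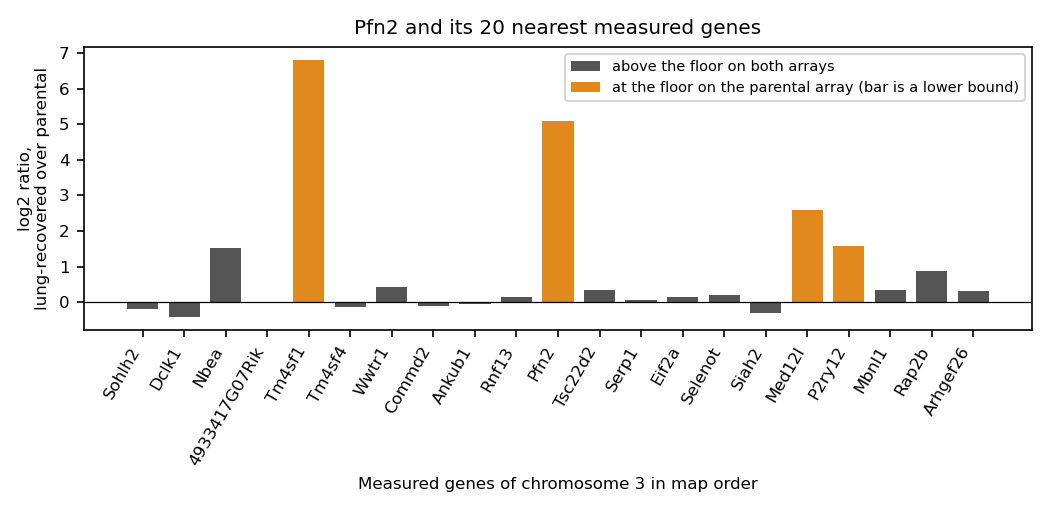
Log2 ratio (lung-recovered over parental, vertical axis) of Pfn2 and its 20 nearest measured genes in map order, with orange bars as lower bounds for genes at the floor of the parental array. Pfn2 at 5.09 and Tm4sf1 at 6.81 stand above the 5 genes between them, which lie between -0.14 and 0.41.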

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

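The comparisons of genes left out 10092 probe sets with no or several gene names, and these also carried signal that differed between the arrays. Of 4043 of them above the floor on at least 1 array, 77 were at least 2-fold higher and 197 at least 2-fold lower in the lung-recovered line, together 6.78%. Among the named genes the share was 6.97%. The units differ, since every unnamed probe set was counted and each named gene only by its brightest. The balance ran the other way from the named genes, of which 589 were higher and 340 lower, and no explanation of this was tested. The probe sets furthest upward were 1422933_at (4.03 and 10.89 log2) and 1420364_at (5.55 and 9.72), and those furthest downward 1427660_x_at (9.07 and 4.22) and 1452417_x_at (8.11 and 3.12).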

How the results depend on the processing

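The random sets and lists without chromosome 12, and the chromosomes without genes past 2-fold, were chosen after seeing the data. None of the 76 named genes past 2-fold changed sign, but 10 of them were under 2-fold in some alternative. These were Ankrd37, Pdgfb, Rtkn2 and Cd68 with the floor at the 60th percentile, Ccn1, Pfkl, Bcl2 and Pdia6 by the median over probe sets, and Ccn1 (0.23), Pfkl (-0.78), Anxa8 (-0.72) and Mvd (0.83) without suffixed probe sets. Another 7, Mx1 and Sox17 among them, had no value in some alternative. Of all 929 genes past 2-fold, 696 kept the call with the floor at the 60th percentile and 781 by the median over probe sets, where 1 and 2 changed sign, and 781 of the 824 still measured did without suffixed probe sets, where 2 changed sign. No list or chromosome that stood apart crossed to the other side, and the medians of all measured genes moved by at most -0.08 log2 under the other scalings. The lists of oxidative phosphorylation, hypoxia and glycolysis, ribosomal proteins, and endoplasmic reticulum and heat stress, and chromosomes 3, 12 and 16, kept their side of the limits under every alternative run on them. For the following the cause was not tested, apart from the floor settings, which set bounds directly. The epithelial list was at percentile 96.38 after quantile normalization, 97.29 without a floor and 87.03 without probe sets of suffix _s, _x or _a, where the actin list was at 88.61 and the integrin list at 95.63. The growth factor list was at 96.71 with the floor at the 60th percentile, and lung epithelial markers at 4.13 for the list mean. Chromosome 6 was at 3.79 after quantile normalization, and chromosome 15 at 2.56 after quantile normalization, 3.36 after lowess and 8.87 with the floor at the 60th percentile. Pfn2 had a log2 ratio of 5.49 with the floor at the 20th percentile, 3.60 at the 60th and 5.42 without a floor. With the floor at the 20th percentile, 18 genes were higher and 26 lower by a bound, and the other counts stayed within 1.5 times those reported, with 340 to 608 higher and 192 to 366 lower above the floor on both arrays and 55.7% to 63.1% of all calls higher. In 13 cases a list, and in 4 a chromosome, that had not stood apart did so, among them mesenchymal transition genes in 5, up to 99.98 without members shared with other lists, and NF-kB targets in 3. Signal near the floor limits dim genes, and control probe sets were not analysed here.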

Other observations

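The gene families and the stretches of chromosome 8 described here were chosen after their values were seen. So were all tests below except that of chromosome 12 after lowess, although the alternatives behind the lowest Pfn2 ratio had been planned.

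Members of several families of neighbouring genes were lower in the lung-recovered line. Of 6 measured Akr1c genes, which encode aldo-keto reductases that act on steroids and other carbonyls, 5 were at least 2-fold lower, from Akr1c13 (10.20 and 8.80 log2, 2.64-fold) to Akr1c18 (37.8-fold), and Akr1c6 read 4.82 and 4.63. Of 3 measured Ugt2b genes, 2 were at least 2-fold lower. Of 10 measured Ms4a genes, which encode small membrane proteins known mostly from leukocytes, Ms4a4b (7.98 and 3.54, at least 10.5-fold), Ms4a4d (8.96 and 6.34, 6.15-fold) and Ms4a6b (7.08 and 3.60, at least 5.62-fold) were lower and 0 were higher past 2-fold, with a median log2 ratio of -0.28. Of 6 measured Sprr genes, Sprr1b and Sprr2h (8.94 and 5.97, 7.84-fold) were lower, while Sprr1a read 13.81 and 13.82 and the family median was close to 0. Other families ran differently, with 2 of 10 measured Cldn genes higher and 0 lower, 3 of 14 Gst genes higher and 1 lower, and both measured Sprouty genes higher, of which Spry2, at 2.01-fold, was under 2-fold after each other scaling and by the median over probe sets. Members of each family are close relatives, so the signal of one can include that of another. The last 96 measured genes of chromosome 8 in map order, from Crispld2 on, had a median log2 ratio of 0.55, or 1.46-fold, with 74 genes above 0. The rest of that chromosome had a median of -0.06 but was not flat. Its lowest median over 51 neighbouring measured genes was -0.32, from F7 to Gpat4.

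Chromosome 12 genes were higher by a median of 0.27 log2. After lowess the median was 0.23. This outcome was near certain, since the median log2 ratio in the 10 equal bins of mean signal ran only from -0.11 to 0.08. A trend with signal of that size could hardly have made the median of chromosome 12. Of its genes, 67.7% were above the median of all measured genes, where at most 54.5% could be if only those past 2-fold had changed. The rise was thus spread over many genes. With a chromosome median of 0.27 already seen, such a share was near certain, so it is no separate test of a few strongly changed genes. The median without genes past 2-fold had been set as that test and decides nothing either, since so few genes can hardly carry a median. In all 10 of 10 blocks of neighbouring genes the median was above that of all measured genes, from 0.16 to 0.41. A gain of the whole chromosome in the lung-recovered line, in all or some of its cells, is a candidate explanation that these values go with. DNA was not analysed here, and whether such a change was selected in the lung or arose in culture was not tested.

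Pfn2 was at least 34.1-fold higher. All 3 of its probe sets were past 2-fold, which argues against one faulty or cross-hybridizing probe set. Its lowest log2 ratio over the alternatives of scaling, floor and probe set rule was 3.60. With signals this far apart these settings could hardly bring it under 2-fold, so this shows only that the call did not depend on them. The 20 nearest measured genes had a median of 0.18, which argues against a gain of the whole surrounding region as the source of a difference of this size. A smaller regional gain was not tested and stays open. Of these neighbours, 4 were past 2-fold upward and 0 downward. On chromosome 3, the highest median over 51 neighbouring measured genes was 0.33, from Naa15 to Mlf1. A change in the regulation of Pfn2 in the lung-recovered cells, or the outgrowth of cells that already expressed it, may underlie the difference, and these were not told apart by any test here. Tm4sf1 lies close to Pfn2 and also came up from the floor, and whether the pair share a cause was not tested.

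Cdh5, Cd68 and Csf1r, markers of endothelial cells and macrophages, were higher in the lung-recovered line, Cd68 under 2-fold (0.87 log2) with the floor at the 60th percentile, and host cells carried over from the lung could bring them. Of the 12 other measured endothelial and 17 other measured leukocyte markers, 0 were past 2-fold upward. These counts were fixed in advance, since Cdh5, Cd68 and Csf1r were singled out as the list members past 2-fold upward. The highest log2 ratio of the other endothelial markers was 0.11 and their median -0.205. Tek, whose probe set read 8.57 on the parental array, was at the floor on the lung-recovered array. For the other leukocyte markers the highest ratio was 0.03 and the median -0.13. The other markers thus did not rise with Cdh5, or with Cd68 and Csf1r, which argues only against cells that would raise them together. Markers at the floor on both arrays were left out of both counts. On the parental array, 11 of 24 endothelial and 18 of 37 leukocyte markers were above the floor already, and a small share of host cells would move those less. Xist, expected in cells of the female hosts, read at most 4.35 on the lung-recovered array, under the floor of 4.59, but it was at the floor on the parental array too, so nothing here shows that its probe sets respond, and a small share of host cells stays open. Expression of these genes by the tumour cells themselves also stays open and was not tested.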
